A study of Mus musculus with 8 samples.

How the data were processed

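The authors deposited 1 table of log2 expression values with 45101 probe sets and 8 arrays, none of them missing, and these values were used as they stood. Per the labels' protocols, RNA of sorted blood monocytes was extracted with TRIzol and RNeasy, amplified, labelled with biotin and hybridised to Affymetrix mouse GeneChip arrays. Per the submitters' processing notes the arrays were read and normalised in R with oligo by RMA and compared with limma, with fgsea for pathways and Benjamini-Hochberg correction. Their versions, the chip definition and the number of cells or mice per array are not given in the sources used here. Raw scans were not reprocessed.

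The descriptions conflict on clodronate liposomes. The series text places depletion 3 days before the beads without setting the subsets apart, whereas the treatment protocol uses it to label classical cells and leaves it out for nonclassical cells. The groups were formed from the labels as Gr1hi or Gr1lo, with or without beads, 2 arrays each. The number of arrays limits precision.

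Of the probe sets, 34945 carried 1 gene symbol and were kept; 932 with several symbols, 9160 without a listed symbol and 64 control probe sets were left out of the gene tests. Of the kept probe sets, 34741 were matched by Entrez number to RefSeq symbols of GRCm38.p6, and 0 symbols changed. For each of 18193 genes the probe set with the highest mean over the 8 arrays stood for the gene; 9010 genes had more than 1. The background level, 6.98, was the 95th percentile of the mean of 112 olfactory, vomeronasal, taste and keratin-associated genes, and 8786 genes had a mean above it. Control probe sets were used for quality only: 24 for the poly-A controls, 18 for the hybridization controls and 3 for 18S RNA.

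Comparisons were fixed before the data were examined. Linear models with 4 group means were fitted to all 8 arrays with lmFit in limma 3.58.1 (R 4.3.3), moderated with eBayes at its defaults (prior degrees of freedom 4.48, residual 4), and corrected by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05. The contrasts were beads against no beads in Gr1hi cells, in Gr1lo cells and averaged over both, the difference between these bead effects, and Gr1lo against Gr1hi without beads, with beads and averaged over bead state. SE stands for the moderated standard error of a log2 difference, and SD for the standard deviation between the arrays of a group. Rises and falls are named for called genes. All tests were two-sided.

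Lists of 26 gene groups were also fixed then: classical and nonclassical monocyte markers, lysosome, phagocytic receptors and machinery, inflammatory NF-kB targets, type I interferon response, MHC class II presentation, tissue macrophage genes, cholesterol efflux and lipid handling, cholesterol biosynthesis, cell cycle, oxidative stress and metal response, trafficking and adhesion receptors, immediate early and stress genes, glycolysis, oxidative phosphorylation, cytosolic ribosome, marrow progenitor and granule genes, and markers of neutrophils, B cells, T cells, NK cells, eosinophils and basophils, platelets, erythroid cells and dendritic cells. Lists with at least 5 measured genes were tested with camera in limma at its preset correlation of 0.01, corrected by Benjamini-Hochberg over lists. Each was repeated with a correlation estimated from the list, with fry, and with fgsea 1.28.0. Members were counted as called over all genes and after correction over the list alone.

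Genes were named by a fixed rule: per comparison the 10 largest rises and falls among called genes above background in at least 1 group with every array of the higher group above every array of the lower, without predicted genes; members of each list with the smallest p; and 11 label check genes, of which 8 were measured. The difference between subsets needed no ordering of arrays. Genes named outside the rule are said to be so.

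Alternatives fixed with the comparisons were leaving out genes under the background level, the mean of all probe sets of a gene, testing every probe set, fitting the compared arrays alone, eBayes with trend and robust estimation, array weights, centring on the median, cyclic loess, the replicate number as a block, and leaving out each array. A replicate term within each subset was added after the data were seen. Control probe sets were compared by exact permutation of bead state within subsets. Bead effects were compared across subsets by Pearson and Spearman correlation. Tables were prepared with pandas 2.3.3 in Python 3.11.15 and drawn with matplotlib 3.10.9.

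Each comparison was tested on simulated data in which 200 of 18193 genes were changed, over 5 runs. Changes of 1 log2 unit were recovered in 99.6% of genes for beads in Gr1hi, 97.6% for beads in Gr1lo, 99.6% for their average and 91.2% for their difference. They were recovered in 98.4% for the subsets without beads, 97.6% with beads and 99.2% on average. At 0.5 log2 units the recovered shares were, in the same order, 61.2%, 45.6%, 89.6%, 16.4%, 58%, 52% and 90.8%. False calls made up 5.3% to 7.3% of calls, and the fitted changes followed the true ones with slopes from 0.997 to 1.003. A shifted list was called in all 5 runs of every comparison. The simulated values were drawn independently, with no correlation between genes or between arrays. The real arrays may hold both, so these shares need not carry over to them.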

Results

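RNA from mouse blood monocytes was hybridised to Affymetrix mouse GeneChip arrays after the mice, male C57BL/6, had been given fluorescent latex beads of 1 µm intravenously. Classical monocytes (Gr1hi, high in Ly-6C) and nonclassical monocytes (Gr1lo, low in Ly-6C) were sorted 4 days later into cells that carried beads and cells that did not. Each of the 4 groups has 2 arrays, 8 in all, and the small number of arrays limits the precision of every value. The array medians lay between 6.12 and 6.19 log2 units, and between 8613 and 8863 of 18193 genes per array were above the background level of 6.98. Arrays of 1 group correlated at 0.9935 to 0.9963 across probe sets, arrays of 1 subset with different bead state at 0.9894 to 0.9956, and arrays of different subsets at 0.9714 to 0.9776. The descriptions differ on clodronate liposomes, which deplete phagocytes: the design text places depletion 3 days before the beads without naming a subset, whereas the treatment protocol reserves it for the labelling of Gr1hi cells. Under the second reading, Gr1hi and Gr1lo cells also differ in pretreatment.

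Measures that are not monocyte transcripts moved with bead state, and the 2 Gr1lo arrays without beads differed from each other. The poly-A control transcripts, bacterial RNAs added during labelling, were at 7.93 ± 0.26 (SD, n = 2) in Gr1hi cells without beads and 9.66 ± 0.28 with beads. In Gr1lo cells they were at 8.98 ± 0.41 without and 10.45 ± 0.01 with beads. Their mean difference over both subsets was 1.60, with a two-sided exact permutation p of 0.0556, the smallest that the 36 assignments of arrays within subsets can give. The hybridization controls differed by 0.20 in Gr1hi and 1.07 in Gr1lo cells (exact permutation p 0.0556). The 3' to 5' differences of Actb and Gapdh probe sets, a sign of RNA degradation, differed with beads by 0.03 and 0 in Gr1hi cells and by 0.17 and 0.15 in Gr1lo cells (exact permutation p over both subsets 0.278 and 0.333). In Gr1lo cells Actb was at 0.57 ± 0.01 with beads against 0.41 ± 0.01 without, and Gapdh at 0.08 ± 0.01 against -0.06 ± 0.03. For the macrophage complement gene C1qa, array 2 of the Gr1lo group without beads read lowest of the Gr1lo arrays. It was at 8.16, against 11.37 on array 1 of that group, and 10.66 and 10.13 on the Gr1lo arrays with beads. For the 18S ribosomal RNA probe sets array 1 was lowest, at 8.58 against 10.13 on array 2, and 10.07 and 10.64 with beads.

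Do Gr1hi monocytes that took up beads differ in expression from Gr1hi monocytes that did not? With beads, Gr1hi cells had more Spic, the transcription factor of iron-recycling macrophages, at 8.74 ± 0.06 (SD, n = 2) against 7.27 ± 0.06, a rise of 1.47 ± 0.11 (SE; limma, Benjamini-Hochberg adjusted p = 0.00836). Slc40a1, which encodes the iron exporter ferroportin, rose by 1.20 ± 0.14 (adjusted p = 0.0259), and Gpnmb, a lysosome-associated glycoprotein of lipid-laden macrophages, rose by 1.40 ± 0.17 (adjusted p = 0.0259). Lipid genes rose as well: Fabp5, a fatty acid binding protein, by 1.34 ± 0.11 (adjusted p = 0.00857), the lipid-sensing nuclear receptor Pparg by 1.14 ± 0.14, the cholesterol exporter Abca1 by 0.89 ± 0.12, and the oxysterol receptor Nr1h3 by 0.98 ± 0.15. Mpo, which encodes the myeloperoxidase of immature myeloid granules, fell by 1.16 ± 0.12 to a level below background (adjusted p = 0.0177). Of 18193 genes, 45 were called at an adjusted p under 0.05, 27 higher and 18 lower, and 1806 had an unadjusted p under 0.05 where chance gives 910. The called genes included 13 with at least a 2-fold difference.

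Among the other large rises in Gr1hi cells were transglutaminase Tgm2 (1.41 ± 0.15), the formin Fmnl2 (1.43 ± 0.20), the mannose 6-phosphate receptor Igf2r (1.19 ± 0.11), the sorting nexin Snx24 (1.12 ± 0.13) and Basp1 (0.98 ± 0.15). Igf2r and Fmnl2 were below background without beads, and Igf2r averaged over all its probe sets differed by 0.63 and lost its call. The other large falls were Abtb2 (-1.03 ± 0.14), the gelatinase Mmp9 (-0.91 ± 0.11), H2-T24 (-0.87 ± 0.11), Cep85 (-0.87 ± 0.09), Kansl1l (-0.84 ± 0.11), the haemoglobin gene Hba-a2 (-0.83 ± 0.11), the interferon-inducible Ifitm1 (-0.77 ± 0.11), Serinc4 (-0.75 ± 0.10) and the kinase Stk26 (-0.72 ± 0.08). With all probe sets of a gene averaged, Abtb2 (-0.40), Kansl1l (-0.26), Serinc4 (-0.45), Cep85 (-0.56), Stk26 (-0.62), Abca1 (0.73), Nr1h3 (0.98) and Basp1 (0.98) lost their calls too. Over 18 alternative settings the call was lost in 13 for Basp1, 10 for Ifitm1 and 9 for Nr1h3. With beads, Abtb2, H2-T24 and Serinc4 were below background.

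Gene lists fixed before the data were examined were tested with camera in limma at its preset correlation, and 13 of 26 passed in Gr1hi cells. Of 19 measured genes of cholesterol efflux and lipid handling, 4 rose and none fell over all genes (11 and 1 adjusted over the list alone). The median of that list was 0.29, with adjusted p = 2.96e-10 in limma's camera and adjusted p = 0.0872 with an estimated correlation. Tissue macrophage genes shifted up (3 of 21 called higher, 4 adjusted over the list alone, median 0.37, camera adjusted p = 1.59e-07), with adjusted p = 0.333 with an estimated correlation. In that list C1qa, C1qb and C1qc differed by 1.36, 1.38 and 1.31 without being called. Their Gr1hi arrays lay close together (C1qb 11.25 and 11.22 with beads, 9.82 and 9.90 without). The fit shares 1 spread per gene over all 4 groups. The Gr1lo arrays without beads, at 12.06 and 9.37 for C1qb, widened it. Lysosome genes had 1 of 36 called, Gpnmb, and 6 higher adjusted over the list alone (median 0.14, camera adjusted p = 1.59e-07), with adjusted p = 0.333 with an estimated correlation. Nonclassical monocyte markers had 3 of 22 called higher, namely Adgre4 (0.90 ± 0.10), Eno3 (0.86 ± 0.12) and Treml4 (0.67 ± 0.09), and 8 higher and 1 lower adjusted over the list alone. Their camera adjusted p was 1.10e-06, and adjusted p = 0.333 with an estimated correlation. Classical monocyte markers had 0 of 17 called and 0 adjusted over the list alone (median -0.23, camera adjusted p = 0.00260), with adjusted p = 0.181 with an estimated correlation. Of the 13 lists that passed camera, fgsea kept 13 and fry 4.

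Interferon genes and the markers of eosinophils and basophils, neutrophils and T cells also shifted in Gr1hi cells. None of 31 type I interferon genes was called and 1 was lower adjusted over the list alone (median -0.32, camera adjusted p = 1.28e-09), with adjusted p = 0.352 with an estimated correlation; Cmpk2 differed by -0.87 and Ifit1 by -0.95. Eosinophil and basophil markers had 3 of 12 called lower and 6 adjusted over the list alone (median -0.42, camera adjusted p = 5.75e-07), with adjusted p = 0.181 with an estimated correlation. The 3 called, the basophil protease Mcpt8 (-1.13 ± 0.12), the IgE receptor chain Ms4a2 (-0.95 ± 0.09) and the mast cell carboxypeptidase Cpa3 (-0.76 ± 0.10), were below background in all 4 groups. Neutrophil markers had 1 of 15 called lower, Mmp9, and 3 adjusted over the list alone (median -0.59, camera adjusted p = 7.47e-07), with adjusted p = 0.157 with an estimated correlation. Marrow progenitor and granule genes had 1 of 13 called lower, Mpo, and 2 adjusted over the list alone (median -0.20, camera adjusted p = 0.0432), with adjusted p = 0.333 with an estimated correlation. T cell markers had 1 of 15 called higher, Cd28 (0.93 ± 0.11), and 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.000858), with adjusted p = 0.157 with an estimated correlation. Cell cycle genes had 0 of 32 called and 1 higher adjusted over the list alone (median 0.15, camera adjusted p = 4.08e-05), with adjusted p = 0.470 with an estimated correlation. Genes of oxidative stress and metal response had 0 of 16 called and 1 higher adjusted over the list alone (median 0.14, camera adjusted p = 0.00281), with adjusted p = 0.165 with an estimated correlation. Cholesterol biosynthesis genes had 0 of 19 called and 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.0143), with adjusted p = 0.491 with an estimated correlation.

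The other 13 lists did not pass in Gr1hi cells. Their camera adjusted p values in limma were 0.0620 for NK cell markers, 0.106 for oxidative phosphorylation, 0.189 for the cytosolic ribosome, 0.260 for phagocytic receptors and machinery, 0.456 for glycolysis, 0.518 for immediate early genes and 0.546 for erythroid markers. They were 0.558 for MHC class II presentation, 0.635 for B cell markers, 0.722 for inflammatory NF-kB targets, 0.935 for platelet markers, and 0.989 for trafficking receptors and for dendritic cell markers. Median, mean and test differed in sign for NF-kB targets, trafficking receptors and dendritic cell markers. The gene count fell to 0 without Gr1hi array 1 or 2 with beads or Gr1hi array 1 without beads, and limma then left 1293, 1335 and 1218 genes at an unadjusted p under 0.05. It was 6 without Gr1hi array 2 without beads and 20 without either Gr1lo array with beads.

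Do Gr1lo monocytes with beads differ from Gr1lo monocytes without? With beads, Slc40a1 was at 9.30 ± 0.30 (SD, n = 2) against 6.32 ± 0.11 without, a rise of 2.98 ± 0.14 (SE; limma adjusted p = 7.68e-05). Gpnmb rose by 2.16 ± 0.17 (adjusted p = 0.00186), the growth factor Igf1 by 1.46 ± 0.14 (adjusted p = 0.00698) and Spic by 1.08 ± 0.11 (adjusted p = 0.00733). Among the called falls, the coagulation factor chain F13a1 went from 10.39 ± 0.31 to 7.35 ± 0.16 (-3.04 ± 0.15, adjusted p = 7.68e-05), and the dendritic cell lectin Cd209a from 9.90 ± 0.24 to 6.76 ± 0.11 (-3.13 ± 0.12, adjusted p = 4.44e-05). The proteoglycan Vcan (-2.97 ± 0.15) and the chitinase-like secreted protein Chil3 (-1.48 ± 0.08) fell as well. Of 18193 genes 41 were called, 15 higher and 26 lower, with 2402 at an unadjusted p under 0.05 and 26 of the called at 2-fold or more.

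**Figure D1:**
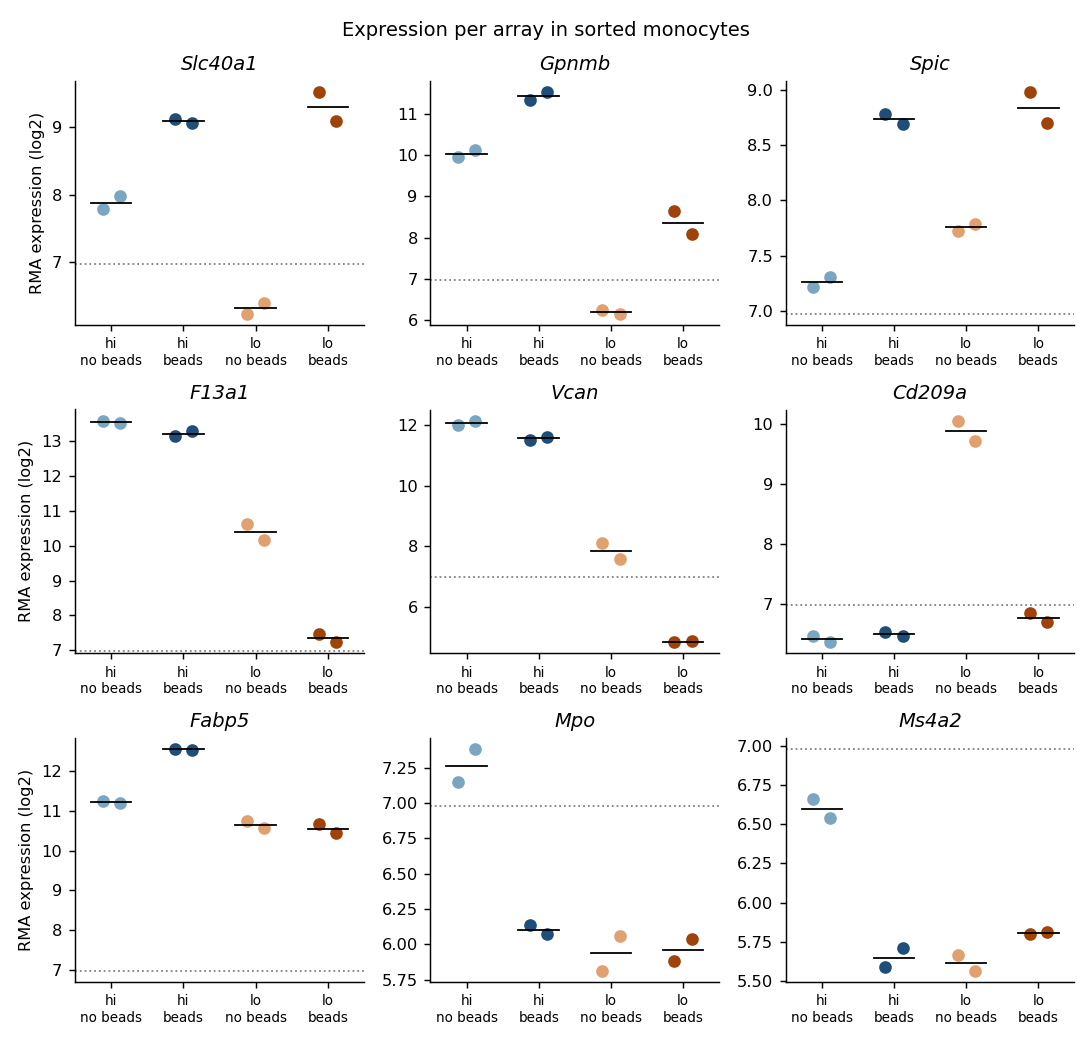
RMA expression (log2, vertical axis) of 9 genes on each of the 8 arrays, in Gr1hi (blue) and Gr1lo (orange) monocytes without beads (light) and with beads (dark); bars mark group means and the dotted line the background level of 6.98. Slc40a1, Gpnmb and Spic were higher with beads in both subsets, and Cd209a was at 9.90 in Gr1lo cells without beads and below background in the other 3 groups.

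Further rises in Gr1lo cells were the guanylate-binding protein Gbp8 (1.69 ± 0.19), the carbonyl reductase Cbr2 (1.43 ± 0.19), the secreted metalloprotease Adamdec1 (1.28 ± 0.17), Snx24 (1.27 ± 0.13), the macrophage membrane protein Ms4a7 (1.03 ± 0.14) and the transcriptional inhibitor Id3 (1.00 ± 0.14). Further falls were the killer cell receptor chain Klrd1 (-2.40 ± 0.12), the neutrophil collagenase Mmp8 (-2.20 ± 0.25), Bex6 (-2.05 ± 0.21), the neutrophil surface protein Cd177 (-1.99 ± 0.29), the platelet and myeloid G-protein regulator Rgs18 (-1.56 ± 0.14) and the small GTPase Rnd3 (-1.53 ± 0.15). Averaged over all of its 8 probe sets, of which 3 were above background, Vcan fell by 0.57 and stayed called; Gpnmb, with 1 of its 2 probe sets above background, rose by 1.19. Ms4a7 averaged in this way differed by 0.55 and lost its call. The call of Cd177 was lost in 14 of 18 alternative settings. Slc40a1, Gpnmb, Gbp8, Igf1, Cbr2 and Snx24 without beads, and Cd209a, Vcan, Klrd1, Mmp8, Bex6 and Cd177 with beads, were below background. The matrix protein Fn1 differed by -3.75 ± 0.68 without being called (adjusted p = 0.0996).

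In Gr1lo cells 12 of 26 lists passed. Classical monocyte markers had 5 of 17 called lower (1 higher and 11 lower adjusted over the list alone, median -0.54, camera adjusted p = 9.04e-13 in limma), with adjusted p = 0.0632 with an estimated correlation. Dendritic cell markers had 3 of 15 called lower, Cd209a, the lectin Clec10a (-1.47 ± 0.19) and Kmo (-1.35 ± 0.11, below background), and 1 higher and 4 lower adjusted over the list alone. Their mean was -0.41 and their median 0.02, opposite in sign, with camera adjusted p = 0.0464, and adjusted p = 0.373 with an estimated correlation. NK cell markers had 1 of 13 called lower, Klrd1, and 2 adjusted over the list alone (median -0.04, camera adjusted p = 0.0469), with adjusted p = 0.425 with an estimated correlation. Tissue macrophage genes had 3 of 21 called higher, Slc40a1, Gpnmb and Spic, and 6 higher and 2 lower adjusted over the list alone (median 0.34, camera adjusted p = 0.00769), with adjusted p = 0.712 with an estimated correlation. The mean shift of that list, 0.34, was 0.98 without Gr1lo array 1 without beads and -0.31 without array 2 of that group. C1qa, C1qb and C1qc differed by 0.63, 0.88 and 0.84, and Cd163 by -2.16, none of them called. The mean difference of the C1q genes was 2.271 without Gr1lo array 1 without beads and -0.705 without array 2 of that group.

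Of the lists that passed downward in Gr1lo cells, 5 had 0 called members. Oxidative phosphorylation had 0 of 41 genes called and 0 adjusted over the list alone (median -0.14, camera adjusted p = 1.67e-08 in limma), with adjusted p = 0.373 with an estimated correlation. Cholesterol biosynthesis had 0 of 19 called and 6 lower adjusted over the list alone (median -0.36, camera adjusted p = 8.10e-07), with adjusted p = 0.373 with an estimated correlation; its regulator Insig1 differed by -0.66. The cytosolic ribosome had 0 of 32 called and 0 adjusted over the list alone (median -0.08, camera adjusted p = 4.52e-05), with adjusted p = 0.0880 with an estimated correlation. MHC class II presentation had 0 of 11 called and 0 adjusted over the list alone (median -0.22, camera adjusted p = 0.0111), with adjusted p = 0.679 with an estimated correlation. Cell cycle genes had 0 of 32 called and 0 adjusted over the list alone (median -0.14, camera adjusted p = 0.0231), with adjusted p = 0.747 with an estimated correlation. Without Gr1lo array 1 without beads the MHC class II shift was -0.01 and the cell cycle shift 0.07, and 7 lists passed. Lipid handling genes had 0 of 19 called and 3 higher adjusted over the list alone (median 0.10, camera adjusted p = 0.0469), with adjusted p = 0.373 with an estimated correlation. B cell markers had 0 of 15 called and 3 higher adjusted over the list alone (median 0.22, camera adjusted p = 0.00708), with adjusted p = 0.373 with an estimated correlation. Eosinophil and basophil markers had 0 of 12 called and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.0464), with adjusted p = 0.586 with an estimated correlation. Of the 12 lists that passed camera, fgsea kept 12 and fry 3.

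The remaining lists in Gr1lo cells had camera adjusted p values in limma of 0.130 for marrow progenitor genes, 0.157 for interferon genes, 0.184 for erythroid markers, 0.267 for glycolysis, 0.334 for nonclassical markers, 0.520 for phagocytic receptors and for trafficking receptors, and 0.840 for NF-kB targets. Platelet markers were at 0.851, neutrophil markers at 0.891, and lysosome, oxidative stress, immediate early and T cell lists at 0.942. Median, mean and test differed in sign for marrow progenitor, phagocytic, platelet, neutrophil, lysosome and oxidative stress lists. The gene count was 354 without Gr1lo array 2 without beads, 17 and 23 without Gr1lo arrays 1 and 2 with beads, and 27 without either Gr1hi array with beads. With every array centred on its median the share of higher calls was 47.7%, against 36.6%.

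Were the bead differences of both subsets alike? Of the 27 genes higher with beads in Gr1hi and the 15 higher in Gr1lo cells, 5 were shared where 0.0223 would be by chance: Slc40a1, Gpnmb, Spic, Snx24 and Gbp8. Of 18 and 26 lower genes 1 was shared, the stress-inducible Ndrg1, against 0.0257 by chance, and 0 genes were called in opposite directions, against 5 and 1 in the same direction. The chance counts take the calls as independent. Both comparisons share 1 estimate of the spread per gene, so these counts may be too low. The shared genes were named after their values were seen. Of the 27 genes that rose in Gr1hi cells, 21 had the same sign in Gr1lo cells, and of the 26 that fell in Gr1lo cells 22 had the same sign in Gr1hi cells. Across the 8786 genes above background, which are not independent replicates, the bead differences of the subsets correlated with Pearson's r of 0.318 and Spearman's rho of 0.292.

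**Figure D2:**
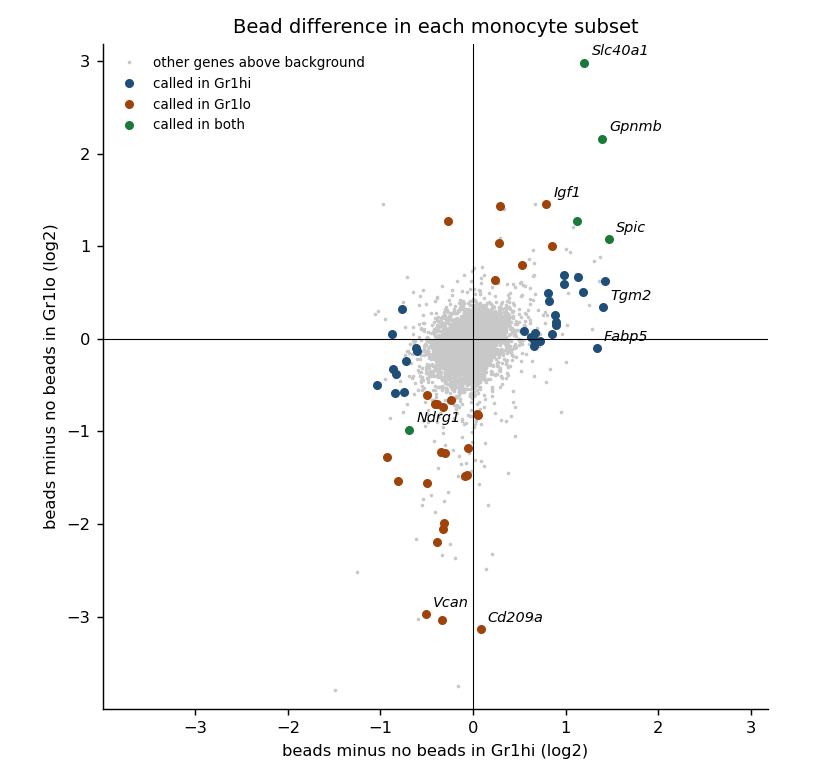
Difference between cells with and without beads (log2) in Gr1hi (horizontal axis) and Gr1lo monocytes (vertical axis) for the 8786 genes above background, with genes called by limma coloured by subset. Slc40a1, Gpnmb, Spic and Ndrg1 were called in both subsets, and Cd209a and Vcan in Gr1lo cells.

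Averaged over both subsets, which asks what beads go with in monocytes at large, Slc40a1 rose by 2.09 ± 0.10 (SE, 4 arrays against 4; limma adjusted p = 0.000272), Gpnmb by 1.78 ± 0.12, Spic by 1.27 ± 0.08 and Igf1 by 1.12 ± 0.10. The osteoclast and macrophage phosphatase Acp5 rose by 0.99 ± 0.11, Pparg by 0.91 ± 0.10 and Nr1h3 by 0.79 ± 0.10. Vcan (-1.74 ± 0.11) and F13a1 (-1.69 ± 0.10) fell, both with adjusted p = 0.000394. Of 18193 genes 139 were called, 50 higher and 89 lower, 17 of them at 2-fold or more, and 2785 had an unadjusted p under 0.05.

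Further rises in the average were Gbp8 (1.60 ± 0.14), Snx24 (1.20 ± 0.10), Fmnl2 (1.03 ± 0.14), Rasgef1b (0.99 ± 0.13), Id3 (0.92 ± 0.10), the lysosomal protease Lgmn (0.58 ± 0.09) and the sterol exporter Abcg1 (0.37 ± 0.06). Further falls were Cd209a (-1.53 ± 0.09), Klrd1 (-1.35 ± 0.08), Mmp8 (-1.29 ± 0.18), Bex6 (-1.19 ± 0.15), Rnd3 (-1.17 ± 0.11), Rgs18 (-1.03 ± 0.10), Ndrg1 (-0.83 ± 0.07), Chil3 (-0.78 ± 0.06) and Stxbp6 (-0.78 ± 0.11). Cd209a and Klrd1 were below background and not called in Gr1hi cells, so their averages rest mainly on Gr1lo cells. The early response gene Ier2 fell by 0.46 ± 0.08.

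In the average 13 of 26 lists passed in limma's camera, 5 up and 8 down, with adjusted p between 0.0911 and 0.491 with an estimated correlation for all 13. Classical monocyte markers had 7 of 17 called lower (1 higher and 11 lower adjusted over the list alone, median -0.38, camera adjusted p = 1.69e-10), with adjusted p = 0.0911 with an estimated correlation. Lipid handling genes had 5 of 19 called higher (10 higher and 1 lower adjusted over the list alone, median 0.25, camera adjusted p = 7.73e-07), with adjusted p = 0.0984 with an estimated correlation. Cholesterol biosynthesis had 0 of 19 called and 8 lower adjusted over the list alone (median -0.19, camera adjusted p = 2.49e-06), with adjusted p = 0.274 with an estimated correlation. Tissue macrophage genes had 3 of 21 called higher and 7 adjusted over the list alone (median 0.34, camera adjusted p = 1.27e-05), with adjusted p = 0.409 with an estimated correlation. Without Gr1lo array 2 without beads that list lost its call, at a shift of 0.14. The gene count was 34, 35, 29 and 36 without Gr1hi array 1 or 2 with beads and 1 or 2 without, 47 and 55 without Gr1lo array 1 or 2 with beads, and 96 and 428 without Gr1lo array 1 or 2 without beads. With arrays centred on their medians 58.3% of calls were higher, against 36%.

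**Figure D3:**
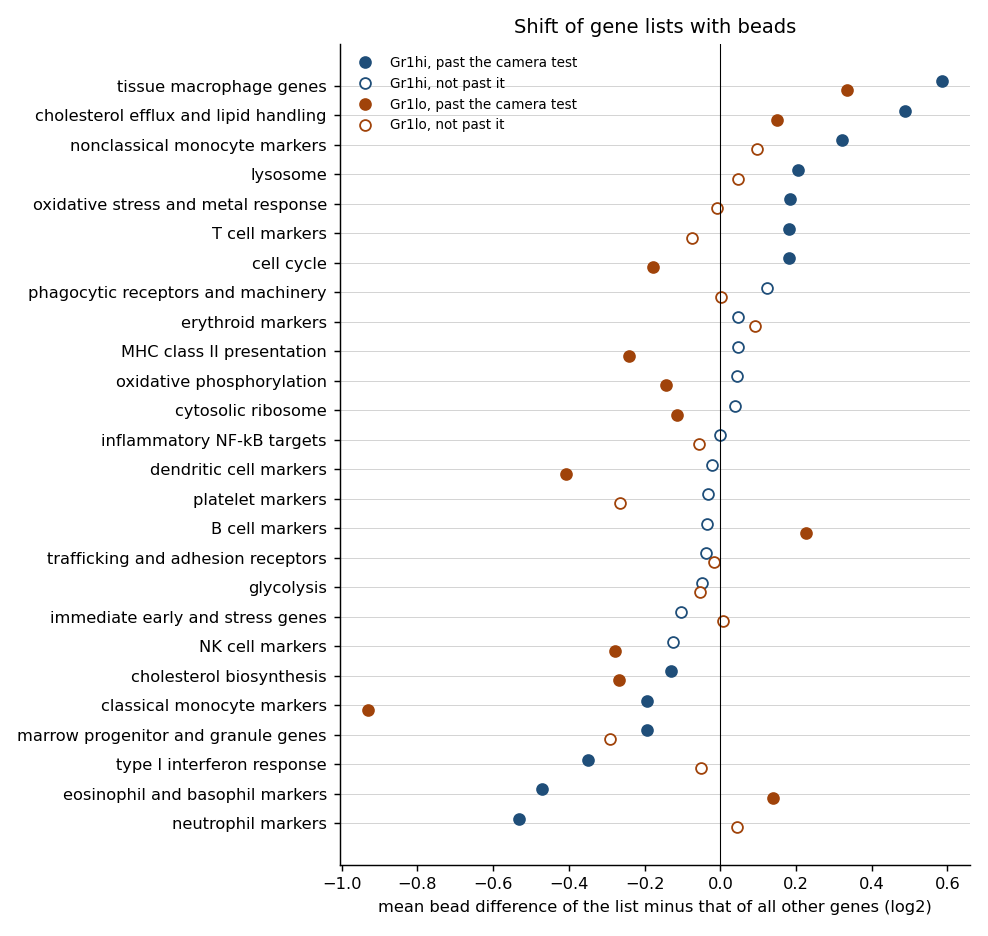
Mean bead difference of each of the 26 gene lists minus that of all other genes (log2, horizontal axis) in Gr1hi (blue) and Gr1lo monocytes (orange); filled points passed limma's camera at its preset correlation, and none passed with an estimated correlation. Tissue macrophage and lipid handling genes lay above 0 in both subsets, and classical monocyte markers below 0.

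The test of the difference, the bead effect in Gr1lo minus that in Gr1hi cells, asks where the subsets differ in what goes with beads. If clodronate was given for the labelling of Gr1hi cells alone, such differences cannot be told apart from those of pretreatment. Cd209a, F13a1, Vcan, Klrd1 and Chil3 fell with beads in Gr1lo cells and were not called in Gr1hi cells, with differences between subsets of -3.21 ± 0.17, -2.71 ± 0.21, -2.46 ± 0.22, -2.10 ± 0.17 and -1.40 ± 0.11 (SE, 2 arrays per group; limma adjusted p = 0.000646, 0.00443, 0.00778, 0.00443 and 0.00443). Cd209a and Klrd1 were below background in Gr1hi cells. Fabp5 rose in Gr1hi cells and was -0.10 in Gr1lo cells, a difference of -1.44 ± 0.15 (adjusted p = 0.0253), and Slc40a1 rose further in Gr1lo cells, by a difference of 1.78 ± 0.20 (adjusted p = 0.0347). Ms4a2, below background in all 4 groups, differed by 1.14 ± 0.13 (adjusted p = 0.0347). These 8 genes, 2 higher and 6 lower, were all that were called of 18193, with 1427 at an unadjusted p under 0.05. Averaged over all its probe sets, Vcan differed by -0.25 and lost its call. The call of the difference was lost for Slc40a1, which was below background in Gr1lo cells without beads, in 11 of 17 alternative settings, and for Ms4a2 in 11 of 16.

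Of 26 lists, 16 passed for the difference between subsets in limma's camera, with adjusted p between 0.0660 and 0.590 with an estimated correlation. Classical monocyte markers had 3 of 17 called lower and 5 adjusted over the list alone (median -0.22, camera adjusted p = 7.01e-09), with adjusted p = 0.0660 with an estimated correlation. Eosinophil and basophil markers had 1 of 12 called higher and 6 adjusted over the list alone (median 0.61, camera adjusted p = 2.09e-08), with adjusted p = 0.180 with an estimated correlation. Oxidative phosphorylation had 0 of 41 called and 0 adjusted over the list alone (median -0.17, camera adjusted p = 1.78e-09), with adjusted p = 0.225 with an estimated correlation. Dendritic cell markers passed downward (camera adjusted p = 0.0102) with a mean of -0.37 and a median of 0.03, opposite in sign, and adjusted p = 0.181 with an estimated correlation. Of the 16 lists that passed camera, fgsea kept 15 and fry 5. The gene count was 3, 4 and 1 without Gr1hi array 1 with beads, array 2 with beads or array 1 without beads, and 167 without Gr1lo array 2 without beads. After cyclic loess 0% of calls were higher, against 25%.

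How do Gr1lo and Gr1hi monocytes differ when neither carries beads? The scavenger receptor Cd36 was at 11.80 ± 0.28 (SD, n = 2) in Gr1lo and 5.58 ± 0.85 in Gr1hi cells, a difference of 6.22 ± 0.37 (SE; limma adjusted p = 1.72e-05). The alarmin chain S100a9 was at 6.23 ± 1.01 in Gr1lo and 12.31 ± 0.19 in Gr1hi cells, lower by a difference of -6.08 ± 0.38 (adjusted p = 2.00e-05). Known markers separated the subsets: Treml4 (4.59 ± 0.09), the peptidase Ace (4.00 ± 0.12), Spn (2.58 ± 0.13), the transcription factor of nonclassical monocytes Nr4a1 (2.21 ± 0.10), the integrin Itgal (1.79 ± 0.10) and the fractalkine receptor Cx3cr1 (1.42 ± 0.11) were higher in Gr1lo cells. The chemokine receptor Ccr2 was lower (-0.83 ± 0.18, adjusted p = 0.00993), and Ly6c1 and Ly6c2 were not analysed here. Of 18193 genes 4288 were called, 1820 higher and 2468 lower in Gr1lo cells, 759 of them at 2-fold or more. With cyclic loess the share of higher calls was 51%, against 42.4%.

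The largest rises from Gr1hi to Gr1lo cells without beads also included the lymphatic growth factor Vegfc (6.06), the ion transporter Slc12a2 (5.77), the fatty acid binding protein Fabp4 (5.70), the sphingosine receptor S1pr5 (5.62), the muscle enolase Eno3 (5.05), the integrin Itgax (4.83), the phosphatase Dusp16 (4.76) and Tgm2 (4.30), with SE between 0.108 and 0.408. Of these, Vegfc, Slc12a2, Fabp4, S1pr5, Itgax and also Cd36 were below background in Gr1hi cells, so the size and order of these differences are uncertain. The largest falls included S100a8 (-5.57), Emp1 (-5.05), Vcan (-4.22), Gpnmb (-3.83), Lcn2 (-3.60), Nt5dc2 (-3.55), the lipoprotein lipase Lpl (-3.53), the cell cycle gene Ube2c (-3.49) and Cd200r4 (-3.43). S100a9, Emp1, Gpnmb, Lcn2, Nt5dc2, Ube2c and Cd200r4 were below background in Gr1lo cells.

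Of 26 lists 15 passed without beads, 7 up and 8 down in Gr1lo cells, all by limma's camera at the preset correlation, with adjusted p between 0.104 and 0.555 with an estimated correlation. Nonclassical monocyte markers had 21 of 22 called higher and 21 adjusted over the list alone (median 2.90, camera adjusted p = 3.46e-33), with adjusted p = 0.104 with an estimated correlation. Classical monocyte markers had 12 of 17 called lower and 1, Ly6i (1.96 ± 0.12), higher (12 lower and 2 higher adjusted over the list alone, median -0.90, camera adjusted p = 5.50e-05), with adjusted p = 0.104 with an estimated correlation. Immediate early genes had 11 of 23 called higher and 12 adjusted over the list alone (median 1.06, camera adjusted p = 8.39e-09), with adjusted p = 0.311 with an estimated correlation. Type I interferon genes had 20 of 31 called lower and 23 adjusted over the list alone (median -0.80, camera adjusted p = 4.45e-06), with adjusted p = 0.408 with an estimated correlation; Oasl1 fell by 1.34 ± 0.12. MHC class II genes had 5 of 11 higher and 2 lower, also adjusted over the list alone (median 0.45, camera adjusted p = 0.000566), with adjusted p = 0.396 with an estimated correlation. Among them H2-Eb1 (3.89), H2-Ab1 (3.80), H2-Aa (3.34) and Cd74 (2.93) were higher in Gr1lo cells. The dendritic cell gene Cd209a (3.49 ± 0.12) and the inflammatory cytokine gene Il1b (2.71 ± 0.21) were also higher. The count was 2631 and 2762 without Gr1hi array 1 or 2 without beads.

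Among bead-carrying cells the subsets differed in 4817 genes, 2152 higher and 2665 lower in Gr1lo cells, 973 of them at 2-fold or more. With cyclic loess the share of higher calls was 50.5%, against 44.7%. The largest rises were Vegfc (6.44 ± 0.18; limma adjusted p = 3.54e-07), S1pr5 (6.18), Slc12a2 (5.48), Cd36 (5.04), the lymphoid factor Ikzf3 (4.96), Dusp16 (4.87), Fabp4 (4.81), Ear3 (4.72), Adamdec1 (4.68) and Itgax (4.44). The largest falls were Emp1 (-7.01 ± 0.48), Vcan (-6.69 ± 0.15), F13a1 (-5.86 ± 0.15), Mmp8 (-5.23), Fn1 (-5.10), S100a8 (-4.62), Slfn4 (-4.26), Gas7 (-4.10), Ednrb (-3.90) and Lcn2 (-3.88). Emp1, Vcan, Mmp8, Gas7, Ednrb and Lcn2 were below background in Gr1lo cells with beads, and Vegfc, S1pr5, Cd36, Ikzf3 and Adamdec1 in Gr1hi cells with beads, so the size and order of their differences are uncertain. The haem oxygenase gene Hmox1 fell by 3.20 ± 0.39 to a level below background in Gr1lo cells. Of 26 lists 14 passed in limma's camera, with adjusted p between 0.125 and 0.607 with an estimated correlation. All 22 nonclassical markers were higher (22 adjusted over the list alone, median 2.80, camera adjusted p = 3.44e-27), with adjusted p = 0.125 with an estimated correlation. Oxidative phosphorylation had 34 of 41 lower, and 34 adjusted over the list alone (median -0.61, camera adjusted p = 1.43e-14), with adjusted p = 0.169 with an estimated correlation. Cell cycle genes had 20 of 32 lower and 1 higher (26 lower and 2 higher adjusted over the list alone, median -0.57, camera adjusted p = 3.94e-07), with adjusted p = 0.373 with an estimated correlation. Lysosome genes had 22 of 36 lower and 1 higher (23 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 1.29e-07), with adjusted p = 0.322 with an estimated correlation.

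Averaged over bead state, 6484 genes were called between subsets, 2684 higher and 3800 lower in Gr1lo cells, 832 of them at 2-fold or more. With cyclic loess the share of higher calls was 50.6%, against 41.4%. Vegfc (6.25 ± 0.12), S1pr5 (5.90 ± 0.08), Cd36 (5.63 ± 0.26), Slc12a2 (5.63 ± 0.13), Fabp4 (5.25), Dusp16 (4.81), Eno3 (4.64), Itgax (4.64), Ear3 (4.47) and Ikzf3 (4.42) led the rises. In the same average of 4 arrays against 4, the falls were led by Emp1 (-6.03 ± 0.34), Vcan (-5.45 ± 0.11), S100a8 (-5.09), S100a9 (-4.87), F13a1 (-4.51), Mmp8 (-4.32), Lcn2 (-3.74), Ube2c (-3.66), Slfn4 (-3.60) and Nt5dc2 (-3.56). In the lower subset Vegfc, S1pr5, Cd36, Ikzf3, Emp1, Lcn2, Ube2c and Nt5dc2 were below background in both bead states, and Slc12a2, Fabp4, Itgax, Vcan, S100a9 and Mmp8 in 1 of them, so the size and order of these differences are uncertain. Of 26 lists 14 passed in limma's camera, 6 up and 8 down, with adjusted p between 0.131 and 0.454 with an estimated correlation. Neutrophil markers had 12 of 15 lower and 1 higher, also adjusted over the list alone (median -1.06, camera adjusted p = 6.75e-05), with adjusted p = 0.131 with an estimated correlation. Trafficking and adhesion receptors had 11 of 19 higher and 4 lower, also adjusted over the list alone (median 0.72, camera adjusted p = 0.000125), with adjusted p = 0.131 with an estimated correlation. Of the 4288 genes called without beads, 3374 were called with beads too, 3371 of them in the same direction, and the differences correlated with Pearson's r of 0.93 across the 8786 genes above background, which are not independent replicates. Klrd1 was higher in Gr1lo cells without beads (1.55 ± 0.12), and with beads it was below background in both subsets.

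**Figure D4:**
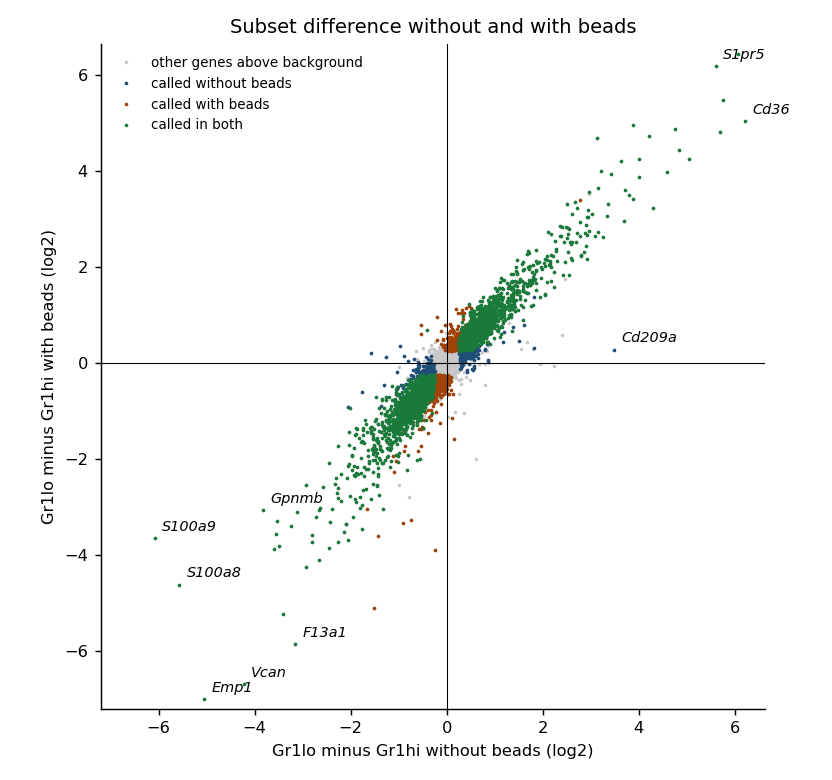
Difference between Gr1lo and Gr1hi monocytes (log2) without beads (horizontal axis) and with beads (vertical axis) for the 8786 genes above background, coloured by the comparison in which limma called them. The differences correlated at 0.93 across genes, and Cd209a stood off the diagonal with 3.49 without beads.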

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

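Tests of RNA input, tissue macrophages, Gr1hi cells in the Gr1lo gate, dim transcripts and other splits of the arrays were set before their results; those of abundant transcripts, of a single array, of basophils and of RNA input on genes taken without regard to spread, and the values of C1q genes without single arrays, were chosen after the result was seen.

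Genes such as Slc40a1, Gpnmb and Spic rose with beads in both subsets while the poly-A controls were higher by 1.60, which raised lower RNA input as a cause. Between arrays of 1 group, the median of the 50 called genes followed the poly-A level with a slope of -0.16 ± 0.22, against 0.564 needed, but these genes had been selected for a small spread within groups, and the 50 genes of largest bead difference taken without regard to spread gave 0.781 ± 0.412, against 0.538 needed, so lower RNA input stays open. Tissue macrophages that had taken up beads and reached the sort could bring such genes: C1qa, C1qb and C1qc differed by 1.07 ± 0.76 on average, against 0.58 for the called genes, with 1.35 in Gr1hi cells, and the average was 1.81 without Gr1lo array 1 without beads and 0.32 without array 2. These tests do not tell apart lower RNA input, tissue macrophages and a response of monocytes. Other differences between cells with and without beads, such as those present before uptake, were not tested. In the 18 splits within subsets, the real one called 139 genes and the highest other 12, too few splits for a share under 0.05.

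Classical monocyte genes fell with beads in Gr1lo cells, and Gr1hi cells in the bead-negative Gr1lo gate may account for this. The 37 other genes high in Gr1hi cells needed a median share of 12.41% of Gr1hi signal (quartiles 3.59% and 23.66%, with 5 at 0 or below, against a single share), between the quartiles of 7.49% and 22.64% of the 5 called classical genes, which ranged from 4.71% for Vcan to 45.48% for Chil3. Against it, S100a8 allowed at most 3% and S100a9 2.51%, with Vcan next at 6.64%. The test asked for 3 of 10 below 4.71% where 2 were, so it did not decide. The limit of Vcan lay below the shares needed by F13a1 (10%), Hp (22.64%) and Chil3 (45.48%). This argues against 1 share of Gr1hi cells as the whole account of those falls, if such cells matched those on the bead-negative Gr1hi arrays. Under the treatment protocol the mice of those arrays received clodronate and the mice of the Gr1lo arrays did not. Whether Gr1hi cells differ for that reason was not tested. As a partial cause, a mixed gate cannot be told apart from a true difference. Cd209a and Klrd1 were below background in Gr1hi cells, so cells like those on the Gr1hi arrays would not supply them. A single outlying array was checked as the sole cause. The 5 called genes had median falls of -1.72 against array 2 alone and -2.67 against array 1, and all 17 measured classical genes -0.44 and -0.65. The 5 genes were selected on both arrays, so their falls exclude nothing. The 12 classical genes not called had median falls of -0.234 against array 2 and -0.345 against array 1. A smaller fall was thus seen against either array.

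Basophil genes were lower with beads in Gr1hi cells. Basophils in the bead-negative gate could bring them, but only 1 of 6 basophil genes, Gata2, was above background (-0.39 ± 0.11), while Cd200r3 differed by -0.05. The median of -0.78 lay at percentile 0 of 10000 lists of like level, but 5 of the 6 genes were below background and the pattern was taken up because they fell, so this does not settle loss of dim transcripts at low RNA input. Basophils in the gate, loss of dim transcripts and a change in monocytes cannot be told apart.

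For the subset difference averaged over bead state, the real split called 5912 genes in a fit of 2 groups. The highest of the other 34 splits called 0 genes, a share of 1 of 35. That fit held no subset term, so every other split put the subset difference into its spread. Low counts were therefore bound to follow, and the splits do not measure chance. The share of 1 of 35 also takes the arrays as independent. Arrays with the same replicate number deviated together within Gr1hi (r 0.601) and within Gr1lo (0.367), so they may not be independent. Chance is therefore not excluded by these splits. In the comparisons without and with beads, which share no array, 3371 of the 3374 genes called in both differed in the same direction. Neither the biological difference between the subsets nor the difference between their bead effects was tested apart from clodronate.

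Other values stood out. The bead effect in Gr1lo minus that in Gr1hi was -3.21 for Cd209a, -2.71 for F13a1, -2.46 for Vcan, -2.10 for Klrd1, -1.44 for Fabp5, -1.40 for Chil3, 1.14 for Ms4a2 and 1.78 for Slc40a1. Among lists that difference was -0.74 for classical and -0.23 for nonclassical monocyte markers, -0.16 for lysosome, 0.30 for interferon, -0.29 for MHC class II, -0.34 for lipid handling, -0.14 for cholesterol biosynthesis and -0.36 for cell cycle genes. It was -0.19 for oxidative stress and for oxidative phosphorylation, -0.16 for the ribosome, 0.58 for neutrophil, 0.26 for B cell, -0.26 for T cell, 0.61 for eosinophil and basophil, and -0.39 for dendritic cell markers. All 16 lists lost their call with an estimated correlation, with adjusted p between 0.0660 and 0.590, and fry kept 5.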

How the results depend on the processing

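Alternatives were fixed before the data were examined, except the replicate term within subsets, which was chosen after the result was seen.

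Without each array in turn, the called genes ranged from 0 to 58 for beads in Gr1hi, 17 to 354 in Gr1lo, 29 to 428 in the average and 1 to 167 for the difference between subsets. The highest values of the last 3 came without Gr1lo array 2 without beads. The subsets without beads differed in 2631 to 4125 genes, and the correlation of bead effects ranged from 0.221 to 0.372. The lists that passed for beads in Gr1lo ranged from 7 to 12. The cause was not tested.

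Trend and robust estimation called 121 genes for beads in Gr1hi, 127 in Gr1lo, 326 in the average and 17 for the difference between subsets. Array weights called 104 in Gr1hi, and a fit of the compared arrays alone called 12 in Gr1lo. Without genes under the background level, 222 genes and 8 lists were called in the average and 5 genes for the difference between subsets; the mean of all probe sets also called 5 for that difference. Over all genes the correlation of bead effects was 0.27.

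Every list lost its call with an estimated correlation, leaving 0 in all 7 comparisons. This included the nonclassical monocyte markers between subsets, nearly all of which were called higher in Gr1lo cells. A call lost in this setting therefore does not set weak lists apart from strong ones. With fry, 4 lists passed for beads in Gr1hi, 3 in Gr1lo, 7 in the average, 5 for the difference between subsets and 22 for the subsets averaged over bead state. Directions turned for the T cell markers between subsets without beads under fry, at a shift of -0.01, for cell cycle genes with beads in Gr1lo without genes under the background level (-0.04), for lysosome genes in Gr1lo under cyclic loess (0.13) and for oxidative phosphorylation in the average under cyclic loess (0.013). Without single arrays the shift in Gr1lo ranged from -0.48 to -0.007 for MHC class II, from -0.42 to 0.068 for cell cycle and from -0.31 to 0.98 for tissue macrophage genes. For tissue macrophage genes in the difference between subsets it ranged from -0.90 to 0.40. The test reversed at -0.007, 0.068, -0.31 and 0.40. The list of eosinophil and basophil markers was not testable without genes under the background level in any of the 7 comparisons.

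With the replicate number as a block, called genes were 56 for beads in Gr1hi, 54 in Gr1lo, 187 in the average and 10 for the difference. Arrays with 1 number deviated together within Gr1hi (r 0.601) and within Gr1lo (0.367), and at 0.036 to 0.09 across subsets. A replicate term within each subset called 102 genes in Gr1hi, 106 in Gr1lo and 332 in the average.

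The settings act after RMA, and normalisation and background correction before it were not varied. Array signal adds background to each transcript, so differences of dim genes are compressed and a value under the background level does not exclude expression.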

Other observations

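The tests cited here were set before their results were seen, except the values without single arrays and the slope of RNA input on genes taken without regard to spread, and the genes brought together here were chosen after their values were seen.

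Slc40a1, Gpnmb, Spic, Snx24 and Gbp8 were called higher with beads in both subsets. Slc40a1 rose by 1.20 in Gr1hi and 2.98 in Gr1lo cells, and Spic by 1.47 and 1.08, while the lipid genes Pparg, Abca1 and Nr1h3 were called in Gr1hi cells and in the average; the difference between subsets was not called for these 3 genes. Spic drives the program of red pulp macrophages, which export iron through ferroportin. A macrophage origin of part of the signal remains possible. C1q genes differed by 1.07 with an error of 0.76, by 1.81 without Gr1lo array 1 without beads and by 0.32 without array 2 of that group. In Gr1hi cells alone they differed by 1.35, and by 1.32 to 1.38 whichever Gr1hi array was left out. In Gr1lo cells alone they differed by 0.783, by 2.271 without array 1 without beads and by -0.705 without array 2. Cd163, another tissue macrophage gene, was lower in Gr1lo cells with beads without being called. Lower RNA input also stays open. Between arrays of 1 group, the 50 genes of largest bead difference followed the poly-A level with a slope of 0.781 ± 0.412, against 0.538 needed. The 95% limits of that slope were -0.53 and 2.093. The 50 called genes gave -0.16 ± 0.22, against 0.564 needed, but these had been selected for a small spread within groups.

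Gr1lo cells without beads carried Cd209a, Clec10a and Klrd1 beside classical genes. Most other dendritic cell and NK cell markers were not called between Gr1lo cells with and without beads. Cd209a was at 9.90 there and 6.76 with beads, and at 6.41 in Gr1hi cells without beads. Since it was below background in Gr1hi cells, a share of 12.41% of cells like those on the Gr1hi arrays could not supply Cd209a. Under the treatment protocol, Gr1hi cells of mice without clodronate were not measured. A further cell type or state in the bead-negative Gr1lo gate was not tested.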
